A study of Citrullus lanatus with 12 samples.

How the data were processed

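The series holds 12 RNA sequencing libraries from anthers of the watermelon variety named in the labels, at the tetrad, mononuclear, dikaryophase and mature stages, with 3 libraries each. Per the labels, flower buds were collected over the flowering period, each anther was staged microscopically on part of the material, RNA was taken from the remainder, and libraries were sequenced on an Illumina HiSeq instrument. Groups and replicate numbers were taken from the library titles and stage labels.

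The deposited table gives a log2 value per gene and library for 23440 gene IDs. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, and neither is the strand setting, so reads shared between near-identical or overlapping genes cannot be assigned with certainty. The values themselves show how they were scaled. For every library, 2 to the power of the deposited log2 value, less a pseudocount of 1, was a whole multiple of a single step for 100% of the values, within a tolerance of 0.01 reads. Each value was therefore the log2 of a read count divided by a factor for its library, plus 1. The factors worked out in this way ran from 0.887 to 1.07, and size factors computed again as medians of ratios differed from them by ratios of 0.994 to 1.01. Normalised reads below are 2 to the power of the deposited value, less 1. Reads per gene were recovered by dividing by the step, giving 55347640 (mature replicate 3) to 65554998 (mononuclear replicate 3) per library, and CPM values were computed from them. All columns belonged to a sample.

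Genes with at least 1 CPM in at least 3 libraries were kept, which left 17484 genes and at least 99.9% of the reads of each library. The tests chosen before the data were examined assumed counts or values per gene length. The deposited values are on a log2 scale, and limma (3.58.1, in R 4.3.3) was fitted to them as deposited. The fit had a mean per stage over all 12 libraries, 8 residual degrees of freedom, and variances moderated with a trend on the mean level. The count-model tests planned for raw read counts were not run, although the recovered reads would have allowed them. P-values were adjusted by Benjamini-Hochberg within each comparison. A gene was called with an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Change over any stage was tested with the moderated F-test. A gene was enriched in a stage when called higher there than in each of the other 3. Fold changes are differences of mean log2(value + 1). The pseudocount draws the change of genes with few reads towards 0, but where the reads of a stage sit mostly in 1 library the difference of log2 means exceeds the ratio of the mean levels (for Cla019426, a log2 fold change of 10.81 against a ratio of means of 269). Where a stage had no read, a lower bound of the fold was computed from CPM against a floor of 3 reads over the 3 libraries of that stage. Such bounds cover counting error only.

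For each of the 4 comparisons, the 2 called genes with the largest rise and the 2 with the largest fall were named, among genes whose stages did not overlap and whose mean over the 12 libraries was at least 10 CPM; the 5 genes with the highest mean in each stage could also be named. This rule, the comparisons, the thresholds and most alternatives were fixed before the data were examined; the fit to log2 values as deposited and the filter on CPM were settled once their scale was known. The gene lists fixed at the same time rest on gene descriptions, which the table does not pair with the IDs, so the gene list tests and the cell type markers were not computed.

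The fit was tested on simulated read counts for the 17484 genes with 100 genes changed 2-fold and 100 changed 4-fold in each comparison. Of genes changed 4-fold, 87% were called for mononuclear against tetrad, 87% for dikaryophase against mononuclear, 93% for mature against dikaryophase and 87% for mature against tetrad. Of those changed 2-fold, 34%, 30%, 40% and 36% were called. Before the fold threshold, which lies at the simulated change, 60%, 60%, 65% and 59% of them passed the adjusted p. Unchanged genes were called 8, 10, 7 and 2 times. Far fewer genes were changed here than passed the adjusted p in the data, 1907 to 7440 in a comparison. The Benjamini-Hochberg adjustment is less strict where more genes change, so the shares above do not give the recovery in the data. Genes were drawn independently, and those not changed kept 1 mean over all stages. Shifts of whole libraries shared by many genes were thus absent, and false calls from such shifts were not measured.

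Alternatives were size factors worked out again, library size as the only scaling, quantile normalisation, median centring, no filter, a filter of 5 CPM, a pseudocount of 0.1, adjusted p alone, an adjusted p under 0.01, a log2 fold change of at least 2, the 2 stages compared alone, the replicate number as a block, and each library left out in turn. Added after seeing the data were limma-voom on the recovered reads, log2(CPM + 1), the leaving out of mononuclear replicate 2 and mature replicate 3 together, the classes of genes high in 2 or 3 stages, and the leaving out of single libraries from the counts of genes on and off. Library measures were compared by exact permutation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.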

Results

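Messenger RNA was measured by sequencing in anthers of watermelon (Citrullus lanatus) at 4 stages of pollen development, with 3 libraries per stage and 12 in all. At the tetrad stage the products of meiosis are still held together, at the mononuclear stage each microspore has 1 nucleus, at the dikaryophase each pollen grain has 2 nuclei, and the mature stage follows. The stage of each anther was read under the microscope on a part of the anther, and the RNA came from the rest. Each library held between 55347640 and 65554998 reads assigned to genes, so a level of 1 CPM (a read count scaled to the library total) stood for 55.3 to 65.6 reads. Of 23440 genes, 2620 had no read in any library, and 17484 reached 1 CPM in at least 3 libraries and were tested. The files do not pair the gene IDs with names, so genes are given by ID, and nothing is said of their function. The labels call the 3 libraries of a stage separate groups of samples and do not say whether they came from different plants, so the p-values measure only the spread between these samples.

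Anthers of the 4 stages had distinct transcriptomes, and neighbouring stages were the more alike. The mean Pearson correlation of log2 levels over the 17484 tested genes was 0.894 between tetrad and mononuclear libraries, 0.868 between mononuclear and dikaryophase libraries and 0.931 between dikaryophase and mature libraries. It was 0.680 between the tetrad and mature ends of the series. Within stages it averaged 0.969, with a lowest value of 0.948 for a pair of mononuclear libraries and a highest of 0.985 for a pair of tetrad libraries. The first principal component held 68.9% of the variance and ordered the libraries from tetrad to mature, and the second held 15.1% and set the tetrad and mature libraries apart from the mononuclear and dikaryophase ones. Mononuclear replicate 2 lay nearer to the later stages on the first component (-43.2) than mononuclear replicates 1 (-65.6) and 3 (-65.2), and mature replicate 3 (107) lay nearer to the dikaryophase libraries than mature replicates 1 (126) and 2 (123). Dikaryophase replicate 3 (58.2) lay nearer to the mononuclear libraries than dikaryophase replicates 1 (73.0) and 2 (82.4), and the cause of its shift was not tested. No pair of libraries within a stage agreed within counting noise: the median squared deviation of a gene between the libraries of a pair was 5.86 to 30.9 in units of counting variance, against 0.455 for counting noise alone. This checks for copied libraries only, since separate samples vary beyond counting noise.

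**Figure D1:**
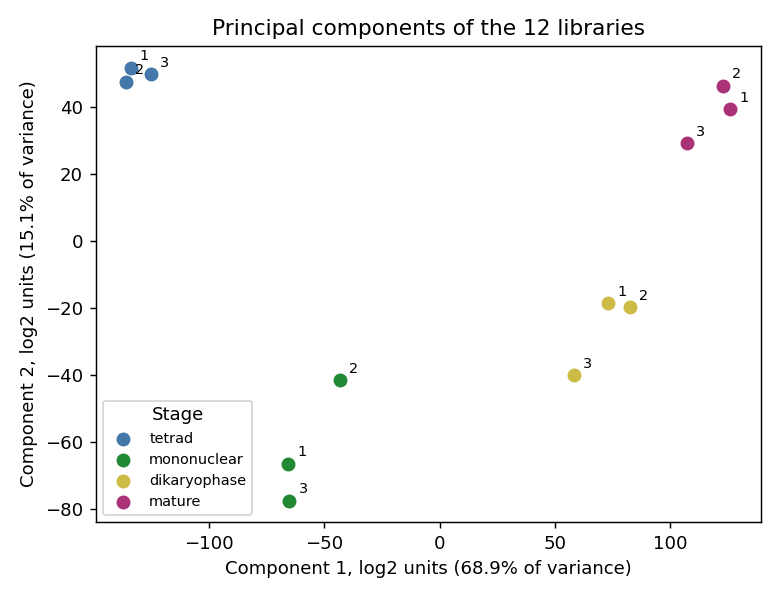
Principal components of the 12 libraries, from log2 levels of the 17484 tested genes. Each point is a library, coloured by stage and numbered by replicate. The first component (68.9% of the variance) runs from tetrad at the left to mature at the right, and mononuclear 2 sits at -43.2 where the other mononuclear libraries sit at -65.6 and -65.2. Dikaryophase 3 sits at 58.2 where the other dikaryophase libraries sit at 73.0 and 82.4.

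The gene with the most reads differed between the tetrad stage, the mononuclear stage and the later stages, and the leading 3 genes were the same at the dikaryophase and maturity (Cla011778, Cla023393 and Cla005669). At the tetrad stage Cla022956 led with 1.09% ± 0.184 of all reads (SD, n = 3), at the mononuclear stage Cla010382 with 2.54% ± 0.632, and at both later stages Cla011778, with 2.70% ± 0.402 at the dikaryophase and 2.13% ± 0.639 at the mature stage. Cla022956 was down to 0.00598% ± 0.00152 at the dikaryophase, while Cla010382 stood at 0.278% ± 0.122 in tetrad and 0.0153% ± 0.00945 in mature libraries. Cla023393 went from 0.0352% ± 0.0229 at the tetrad stage to 2.17% ± 0.330 at the mononuclear stage and held 1.07% ± 0.285 at maturity. Cla005669 was abundant throughout, between 0.740% ± 0.197 and 0.865% ± 0.152 of reads, and did not pass the test of a change over stages (limma F-test, adjusted p = 0.901). The 10 most abundant genes of a library together took 7.14% ± 0.579 of reads at the tetrad stage, 12.0% ± 1.31 at the mononuclear stage, 8.65% ± 0.804 at the dikaryophase and 6.10% ± 0.618 at the mature stage (SD, n = 3 each). An exact permutation test over the 15400 groupings of the 12 libraries into 4 groups of 3 gave p = 0.000130, and 0.000487 after Benjamini-Hochberg adjustment over the 5 library measures tested.

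**Figure D2:**
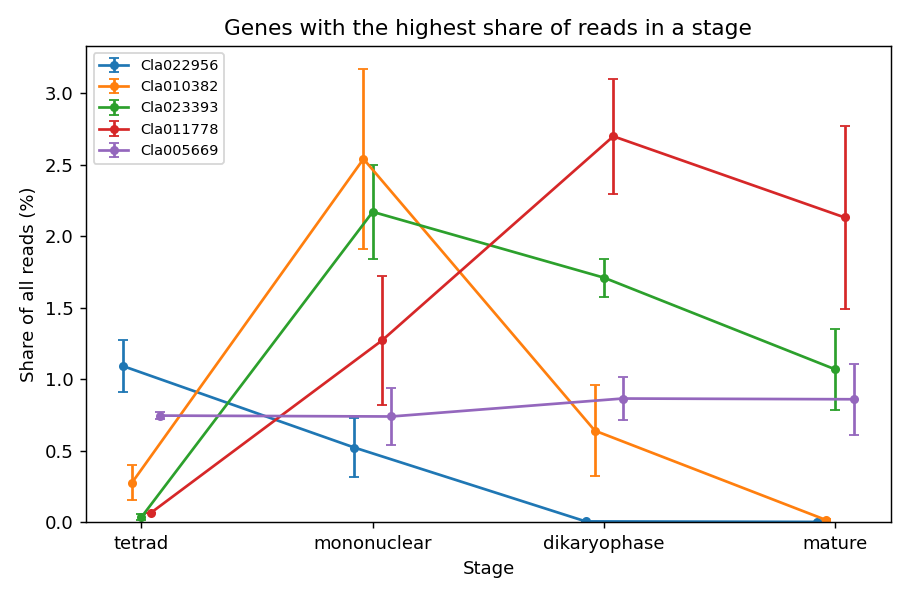
Share of all reads (%) taken by 5 of the most abundant genes at each stage. Points are means of 3 libraries and bars are SDs. Cla022956 is highest in tetrad libraries (1.09%), Cla010382 in mononuclear ones (2.54%) and Cla011778 at the dikaryophase (2.70%), and Cla005669 stays between 0.740% and 0.865%.

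Over all stages, 7791 of the 17484 tested genes differed between at least 1 pair of stages (limma F-test, Benjamini-Hochberg adjusted p under 0.05). The highest mean fell at the ends of the series for most of them: 2796 genes (35.9%) were highest in tetrad and 2845 (36.5%) in mature anthers. The mononuclear stage held the highest mean of 1362 genes (17.5%) and the dikaryophase that of 788 (10.1%). The order of these 2 middle stages depended on the scaling: with library size only they held 850 and 1022, and on the log2(CPM + 1) scale 855 and 1028. With an adjusted p under 0.01 the dikaryophase held 492.

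With the deposited values, the largest changes from the tetrad to the mononuclear stage were mostly rises. Of 1571 genes called, 869 rose and 702 fell, and rises of at least 32-fold numbered 127 against 13 such falls. Counts of 32-fold changes, here and below, were not worked out under the alternatives. Without mononuclear replicate 2 the calls were 859 rises and 825 falls. Cla011397 had no read in the 3 tetrad libraries and 9119 ± 2353 normalised reads in the mononuclear ones, at least 8462-fold higher against a floor of 3 reads over the stage. Cla002945 rose from 29.7 ± 11.9 to 257095 ± 99185 normalised reads, a log2 fold change of 13.05 ± 1.29 (SE from the spread pooled over all 4 stages, n = 3 per stage, limma adjusted p = 3.82e-05). Its widest spread was among mature libraries (51 to 8175 reads), which are not part of this comparison. It had 18 to 40 reads in tetrad and 162830 to 351647 in mononuclear libraries. Among the falls, Cla022664 went from 3662 ± 1496 to 40.9 ± 33.1 normalised reads (log2 fold change -6.65 ± 0.90, limma adjusted p = 0.000356), and Cla015675 from 366156 ± 109959 to 6494 ± 6794 (log2 fold change -6.29 ± 0.54, limma adjusted p = 1.23e-05). In both, mononuclear replicate 2 held the most reads of the mononuclear libraries, 70 for Cla022664 and 12718 for Cla015675, against lowest values of 18 and 2195. Without it the log2 fold changes were -7.25 and -7.12. The 3 libraries of one stage did not overlap those of the other in 1555 of the called genes (99.0%). Calling itself selects for such genes, so their share is no separate support, here and below. Over all genes tested the share was 37.9%, where chance gives 10%. The split of rises and falls was not stable: 55.3% of the called genes rose with the deposited values, 46.3% with library size as the only scaling, 49.8% with limma-voom and 42.9% on a log2(CPM + 1) scale, which changes both the scaling and the offset.

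From the mononuclear stage to the dikaryophase, 1111 genes were called, 605 higher and 506 lower at the dikaryophase. Cla006625 had no read in the mononuclear libraries and 5493 ± 3621 normalised reads at the dikaryophase (SD, n = 3), at least 5716-fold higher against a floor of 3 reads over the stage. Cla019426 rose from 37.9 ± 65.7 to 10205 ± 6218 (log2 fold change 10.81 ± 1.49, SE, limma adjusted p = 0.000657), and all 101 of its mononuclear reads were in replicate 2. Cla001587 fell from 4766 ± 2900 to 11.8 ± 17.2 normalised reads (log2 fold change -9.59 ± 1.15, limma adjusted p = 0.000280), and Cla021856 from 168145 ± 74686 to 435 ± 361 (log2 fold change -8.93 ± 0.62, limma adjusted p = 1.11e-05). Changes of at least 32-fold made up 144 of the rises and 61 of the falls. Stages did not overlap in 1100 of the called genes (99.0%), which calling selects for, and in 25.8% of all genes, where chance gives 10%. Mononuclear replicate 2 held reads of genes that the other 2 mononuclear libraries lacked: 79 genes with at least 500 normalised reads in each dikaryophase library lay at least 50-fold below it in both other libraries, and stood in replicate 2 at a median of 7.84% of the dikaryophase level. With library size as the only scaling, the median of all genes moved by -0.14 from tetrad to mononuclear and by 0.15 from mononuclear to dikaryophase. The small majority of rises to the dikaryophase was not stable: 54.5% of the called genes rose with the deposited values and 64.4% with that scaling, but 49.3% with quantile normalisation, 49.9% without mononuclear replicate 1 and 46.4% with adjusted p alone. Cla006625, Cla019426 and Cla001587 were not called by limma-voom on the read counts, with adjusted p of 0.0702, 0.0831 and 0.163; over all 24 alternatives their adjusted p went down to 6.58e-06, 7.98e-07 and 6.55e-05.

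From the dikaryophase to the mature stage 863 genes were called. Of these, 337 rose and 526 fell, and 29 falls but 0 rises reached 32-fold. Cla009691 rose from 353 ± 246 to 2924 ± 354 normalised reads (SD, n = 3), a log2 fold change of 3.38 ± 0.60 (SE, limma adjusted p = 0.00439). Cla016966 went from 875 ± 1008 to 6153 ± 453 (log2 fold change 4.05 ± 1.11, limma adjusted p = 0.0379), with 44 to 2063 reads in single dikaryophase libraries. Its call was lost in 12 of the 24 alternatives, with adjusted p from 0.00646 to 0.118 over all 24. Cla002945, which had risen at the mononuclear stage, fell from 133579 ± 19215 to 3014 ± 4694 (log2 fold change -7.73 ± 1.29, limma adjusted p = 0.00328). Cla011600 fell from 141679 ± 54997 to 1952 ± 2618 (log2 fold change -7.39 ± 0.92, limma adjusted p = 0.000640). In both, mature replicate 3 held the most reads of the mature libraries, 8175 for Cla002945 and 4806 for Cla011600, against lowest values of 51 and 138. Without it the log2 fold changes were -9.61 and -8.70. Stages did not overlap in 845 of the called genes (97.9%), which calling selects for, and in 29.3% of all genes, where chance gives 10%. Without dikaryophase replicate 3 the comparison called 519 genes and kept 58.9% of the 863. The predominance of falls was not stable: 39.0% of the called genes rose with the deposited values, 53.1% of 1035 with limma-voom and 50.4% of 895 on the log2(CPM + 1) scale.

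**Figure D3:**
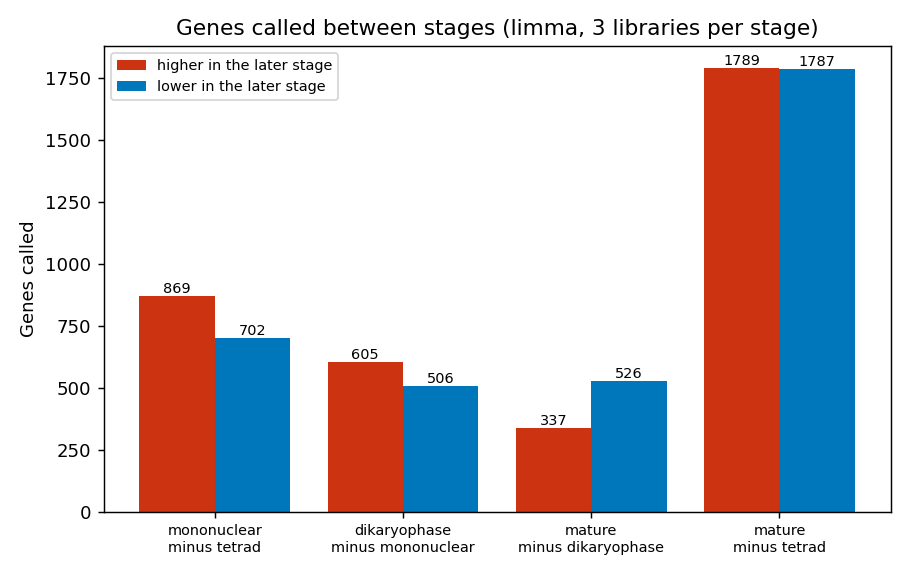
Genes called higher (red) or lower (blue) in the later of 2 stages, by limma with 3 libraries per stage (Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold). The ends of the series differ in 1789 higher and 1787 lower genes, and the last step has 337 higher and 526 lower, a split that limma-voom turned to 53.1% higher.

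Between the ends of the series, tetrad and mature anthers differed in 3576 genes, 1789 higher and 1787 lower at maturity. Cla022598 had no read in tetrad libraries and 40178 ± 2247 normalised reads in mature ones (SD, n = 3), at least 40737-fold higher against a floor of 3 reads over the stage. Cla005213 rose from 5.26 ± 9.11 to 120758 ± 21706 (log2 fold change 15.51 ± 1.64, SE, limma adjusted p = 1.61e-05), with all 16 of its tetrad reads in 1 library. That SE also holds the spread of its mononuclear libraries (31 to 5849 reads), which are not part of this comparison. In the other direction, Cla011332 went from 14809 ± 2618 normalised reads to none, at least 14879-fold lower at maturity, and Cla021877 from 192452 ± 74142 to 25.3 ± 24.6 (log2 fold change -13.16 ± 0.70, limma adjusted p = 1.04e-07). Rises of at least 32-fold numbered 385 and such falls 214. Stages did not overlap in 3540 of the called genes (99.0%), which calling selects for, and in 56.7% of all genes, where chance gives 10%.

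Genes that marked a single stage were mostly those of the ends. A gene counted as enriched when it was called higher in a stage than in each of the other 3, which held for 960 genes: 548 in tetrad, 110 in mononuclear, 8 in dikaryophase and 294 in mature anthers. For 442 of the 548 tetrad genes the mononuclear stage came next, and for 258 of the 294 mature genes the dikaryophase did. Together the tetrad-enriched genes took 8.89% ± 0.739 of all reads in tetrad and 0.677% ± 0.0235 in mature libraries (SD, n = 3), and the mononuclear-enriched genes 4.64% ± 0.446 in mononuclear against 0.684% ± 0.192 in tetrad libraries. The mature-enriched genes went from 0.258% ± 0.000547 in tetrad to 3.17% ± 0.339 in mature libraries. The number enriched at maturity changed with single libraries: it was 152 without dikaryophase replicate 3, 178 without mature replicate 1 and 188 without mature replicate 2, and 470 with mononuclear replicate 2 and mature replicate 3 both left out. For the dikaryophase it ranged from 2 to 20 when libraries were left out in turn.

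Other genes were high over 2 or 3 neighbouring stages. This grouping was chosen after the values were seen, and the classes overlap in part. By the same calls, 305 genes were higher at both the tetrad and mononuclear stages than at both later ones, 151 were high at the mononuclear stage and the dikaryophase, and 480 at the dikaryophase and maturity. Another 494 genes were high at every stage after the tetrad, and 255 at every stage before maturity. All 5 counts followed the thresholds: with adjusted p alone they were 565, 235, 667, 851 and 646, and with a log2 fold change of at least 2 they were 175, 74, 317, 289 and 85, in the order given. On the log2(CPM + 1) scale the last 2 were 296 and 163. The 305 early genes took 12.2% ± 1.97 of reads in tetrad, 6.99% ± 2.01 in mononuclear, 1.07% ± 0.269 in dikaryophase and 0.363% ± 0.00826 in mature libraries. The 480 late genes went the other way, from 0.180% ± 0.00647 through 0.449% ± 0.145 and 3.56% ± 0.648 to 9.18% ± 1.69. Classes that skip a stage were smaller: 39 genes were high at every stage but the mononuclear one, 4 at every stage but the dikaryophase, 8 in tetrad and mature anthers alone, 1 in mononuclear and mature anthers and 0 in tetrad and dikaryophase anthers. Over all alternatives these counts ranged from 12 to 67, from 0 to 21, from 0 to 38, from 0 to 9 and from 0 to 1. The 39 became 63 without mononuclear replicate 2. The 8 became 16 without mononuclear replicate 2, 2 without dikaryophase replicate 3, 4 without tetrad replicate 2, and 5 without tetrad replicate 3 or mononuclear replicate 1. Since the classes were picked on these libraries, the shares describe them and are no separate evidence of direction.

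**Figure D4:**
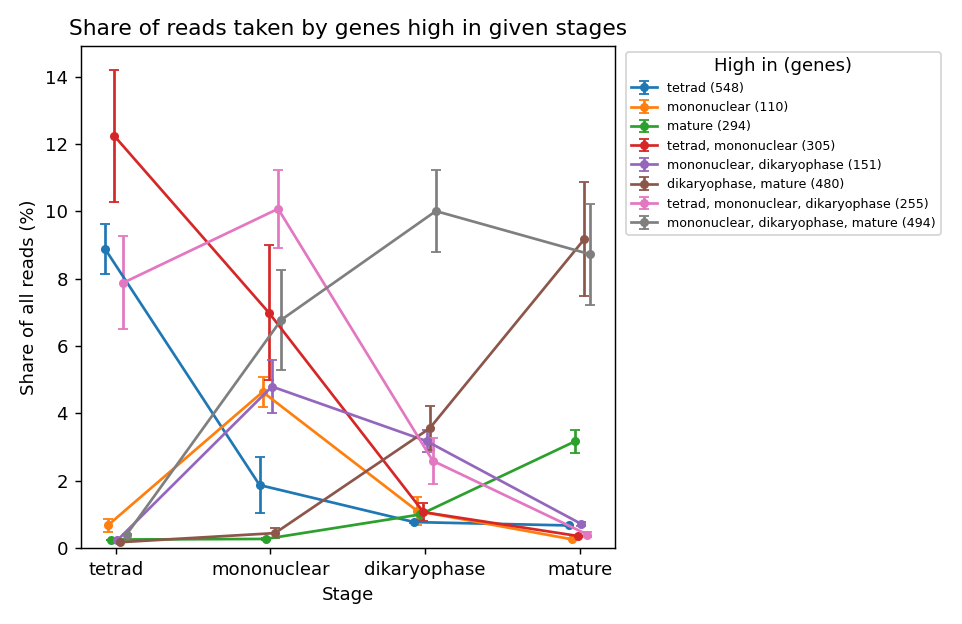
Share of all reads (%) taken at each stage by the 8 classes that hold at least 100 genes, named by the stages in which their genes were called higher than in all others. Points are means of 3 libraries and bars are SDs. The 305 genes high in tetrad and mononuclear anthers go from 12.2% to 0.363% of reads, and the 480 high at the dikaryophase and maturity from 0.180% to 9.18%.

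Some genes were on at one stage and off at another. Counting a gene as off with at most 3 reads in each library of a stage and as on with at least 10 CPM in each, 70 genes were off in tetrad and on in mature anthers, and 13 were on in tetrad and off in mature anthers. Between tetrad and dikaryophase, 39 were off and then on and 6 on and then off. From the tetrad to the mononuclear stage 3 genes came on, from the mononuclear stage to the dikaryophase 2, and from the dikaryophase to maturity 0. Single libraries set several of these counts, as seen when each was left out after the data were examined. The rule must hold in every library of a stage, so leaving out a library can only keep or raise a count. Without mononuclear replicate 2, 34 genes came on from the mononuclear stage to the dikaryophase in place of 2, and 9 did without dikaryophase replicate 3. Between tetrad and dikaryophase, 67 genes came on without tetrad replicate 3, and 11 went off without dikaryophase replicate 1. Leaving out tetrad replicate 3 also raised the genes off in tetrad and on in mature anthers from 70 to 104. Without mature replicate 1, 22 genes were on in tetrad and off in mature anthers, and without tetrad replicate 2 or 3, 5 came on at the mononuclear stage. At these depths 1 CPM stands for 55.3 to 65.6 reads, so off means at most 3 reads, far below 1 CPM, and not absent.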

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

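The fits by limma-voom, on log2(CPM + 1) and without mononuclear replicate 2 and mature replicate 3 together were chosen after the data were seen. No gene called in the 4 comparisons changed sign in any setting run. The count of changing genes uses no fold threshold, so settings of that threshold were left out for it. Of 264 alternative values for the counts and correlations, 226 stayed within 1.5 times the reported count or within 1 SD. With adjusted p alone the calls were 3150 (mononuclear minus tetrad), 1907 (dikaryophase minus mononuclear), 1918 (mature minus dikaryophase) and 7440 (mature minus tetrad), and with a log2 fold change of at least 2 they were 754, 616, 276 and 1718, as the threshold sets. Enriched genes numbered 2267 with adjusted p alone (1200 tetrad, 309 mononuclear, 28 dikaryophase, 730 mature) and 336 with a log2 fold change of at least 2 (224, 35, 0, 77). At an adjusted p under 0.01, mature minus dikaryophase had 512 calls, with 2 genes enriched at the dikaryophase and 149 at maturity. With limma-voom 19 and 501 were enriched at these stages, on log2(CPM + 1) 22 at the dikaryophase, and without mononuclear replicate 2 and mature replicate 3 5 and 470; the cause was not tested. The mean correlation within stages was 0.927 over the 500 most variable genes.

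Leaving out each library in turn gave 1349 to 1684, 859 to 1136, 519 (without dikaryophase replicate 3) to 1024 and 3383 to 3662 calls in the order above, 6527 to 8013 changing genes, and 794 to 1056 enriched genes (436 to 611 tetrad, 91 to 130 mononuclear, 2 to 20 dikaryophase, 152 to 379 mature). Of 384 alternative values for named genes, 15 lost the call and 0 changed sign: 12 for Cla016966 and 1 each for Cla006625, Cla019426 and Cla001587.

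With a replicate block the counts were 1582, 1118, 919 and 3598, with 8104 changing and 990 enriched genes, and of the named genes Cla016966 lost its call. Deviations of same-numbered libraries correlated across genes at -0.11 to 0.36 (mean 0.0408, against -0.0206 for other numbers). They were above 0.1 in 6 of 18 pairs, which include all 3 of the mononuclear and dikaryophase libraries (0.113, 0.150 and 0.175). Only 4 of 12 libraries correlated best with their own number, as many as chance gives on average. The highest was that of dikaryophase and mature replicates 3 (0.364). Mononuclear and mature replicates 3 correlated at 0.164, and dikaryophase and mature replicates 2 at 0.103. Dikaryophase and mature replicates 3 both lay towards earlier stages on the first component. The numbers thus do not pair the samples over all stages. Links between mononuclear and dikaryophase libraries, and among replicates 3 after the tetrad stage, are hints only. The range of the correlations between other numbers was not worked out, so whether these stand out is not shown.

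Among the 10 splits of the 6 libraries of 2 stages, fitted alone with limma, the real stages gave 1569, 934, 793 and 3594 calls and the highest other 0; 10 splits are too few for a share under 0.05. Of 100 groupings of the 12 libraries, 1, the real one, gave as many changing genes (7791, highest other 2161) or enriched genes (960, highest other 134). A share of 1 in 100 is the smallest that these groupings can give, so chance is unlikely for these counts but not excluded. How depth affects calls by level was not tested. The count-model and gene list tests were not run.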

Other observations

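The tests in this part were chosen after the patterns were seen; the outcomes of the thinning of reads and of the ratios between consecutive genes were predicted before they were computed. The 10 genes with the highest mean in mononuclear libraries took 3.68% ± 0.630 of reads in tetrad, 11.9% ± 1.22 in mononuclear, 7.59% ± 0.791 in dikaryophase and 4.49% ± 0.589 in mature libraries (SD, n = 3). The sum covers genes that moved apart. Cla021099 stood at 0.902% ± 0.210 in tetrad and 0.799% ± 0.121 in mononuclear libraries, which overlapped. It was down to 0.300% ± 0.0446 at the dikaryophase, where Cla011778 had its highest mean (2.70% ± 0.402). Of the 5 most abundant genes of each stage, 3 were shared by the mononuclear stage and the dikaryophase, 3 by the dikaryophase and maturity, and 1 by the tetrad and mononuclear stages. The number of genes with at least 10 reads was lowest in tetrad libraries, 18066 ± 10.8, and highest at the dikaryophase, 18403 ± 11.8 (exact permutation p over 15400 groupings 0.000195, adjusted 0.000487).

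Mononuclear replicate 2 held more of some transcripts of both neighbouring stages than the other mononuclear libraries. The 79 late genes described above, chosen to be low in the other 2 libraries, stood there at a median of 7.84% of their dikaryophase level, and of 255 dikaryophase-high genes chosen without the mononuclear libraries, 59.6% were higher in replicate 2, with a median log2 ratio of 0.63 (quartiles -0.35 and 3.63). A constant share of a dikaryophase library carried over would keep these genes in the proportions of that library, but the log2 ratio to any dikaryophase library had an SD over the 79 genes of at least 1.76, against at most 0.776 between dikaryophase libraries. A sample older as a whole would have less of the early transcripts, but 161 tetrad-high genes, chosen without the mononuclear libraries, had a median log2 ratio of 1.32 to the other 2 libraries (quartiles 0.98 and 1.81). The same ratio was -1.39 for mononuclear replicate 1 and -0.48 for replicate 3. The 1.32 of replicate 2 thus also rests on the low levels in replicate 1. What stays open is that the sample of mononuclear replicate 2 may span a wider range of stages than the others, as a hypothesis. In it, late genes that rose less from the dikaryophase to maturity stood at a median of 10.8% of the dikaryophase level. Those that rose more stood at 3.02% (Spearman rho of -0.753 across the 79 genes, which are not independent replicates).

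Mature replicate 3 lay towards the dikaryophase, with a slope of 0.245 along the difference between the stages, against -0.0899 and -0.156 for mature replicates 1 and 2. Each slope was taken against another mature library, so the negative values largely restate the positive one and are no independent comparison. Mature replicate 3 had the lowest read total, but its slope was 0.247 after every library was thinned to the same total. A small share of dikaryophase material, 5.35% by genes that another mature library lacked, would leave mature-high genes at a ratio of at least 0.946 if mature libraries were otherwise alike, and their median ratio to another mature library was 0.658 (quartiles 0.354 and 0.932, 144 ratios). The third quartile lay below that bound, but the other mature libraries differed too (median ratio of 0.833 of replicate 2 to replicate 1 over 27 mature-high genes chosen in replicate 3), and with the bound lowered by this ratio, after the values were seen, it did not. Mixed material thus cannot be told apart from anthers that were less advanced as a whole, which may account for both shifts and was not tested.

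Genes with consecutive ID numbers were in the same class of high stages more often than chance gives. For this count each gene had 1 class at most. The 510 genes in 2 classes and the 57 in 3 were counted only in the class with the fewest stages. Of 14376 consecutive pairs of tested genes, 121 shared a class, against a mean of 31.4 and a highest value of 52 in 9999 permutations of the classes (p = 0.0001, the smallest they can give), and 27 of 13446 pairs that lie 50 numbers apart did. Reads shared by near-identical copies would keep the ratio of both genes constant over libraries; this held for 10.7% of the 121 pairs (SD of the log2 ratio under 0.2), against 1.04% of random pairs of the same class, so sharing may account for some pairs and cannot be told apart from separate expression without sequences. What the numbers say of position on the genome was not examined, and no biological explanation was tested.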
